A study of Caenorhabditis elegans with 2 samples.

How the data were processed

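RNA from Caenorhabditis elegans larvae was measured in 2 libraries, 1 from an lsm-1(tm3585) mutant and 1 from the N2 wild type, both at the L3 stage. Per the labels, the animals were synchronised as L1 larvae and grown for 26 hours at 25 °C, and the mutant had been backcrossed to N2. Per the labels' protocols, total RNA was purified, ribosomal RNA was depleted and libraries were made with an Illumina TruSeq RNA kit. The submitters' processing notes name TopHat, Cufflinks and Cuffdiff without versions. The genome build and the annotation are not given in the sources used here, so no coordinates are printed, and chromosomes are given as in the deposited file.

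The authors deposited 1 table of 46135 genes with 2 pairs of FPKM columns, that is fragments scaled by transcript length and by the size of the library. The pair that stands beside the authors' test was used for every comparison. A further pair entered in 2 places: the limit to genes above 0 in all 4 FPKM columns, and the share of ribosomal RNA, for the 4 genes marked as having too many data, which are listed at 0 in the first pair. That further pair, from the same libraries, was mostly lower by a constant factor, with a median ratio of 1.14 in both libraries, and was otherwise used as an alternative. Its values for the 4 genes were multiplied by that ratio. The authors also deposited a log2 fold change, a test score, a p-value and a q-value per gene. The deposited status column gave a usable test for 17570 genes. The other genes were marked as not tested (26863), failed (1128), too few data (570) or too many data (4). A gene was counted as past the authors' test where the deposited call said so. That test compares the reads of 1 library with those of 1 other library, and so it compares these libraries and not the genotypes. No p-value was computed here, since there was 1 library per genotype and the differences have no replicate check.

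Differences were computed as log2(FPKM + 1) in the mutant minus log2(FPKM + 1) in the wild type, which understates the change of low genes. Genes with an FPKM of at least 1 in either library were called measured (14838 genes). Their median difference was 0.24, a factor of 1.18. With both libraries scaled to the same sum it was 0.11, and the ribosomal RNA shares alone predict 0.20, so this shift is not read as higher expression. By RNA class the median was 0.26 for protein-coding genes, -0.27 for ncRNA, -0.12 for pseudogenes and -0.66 for antisense RNA. A centred difference is the difference minus that median. The size rule counted measured genes with a difference of at least 1, which is 2-fold on this scale. An FPKM of exactly 0 can be a failed estimate, because genes that every cell uses also stood at 0, and such a gene is described as listed at 0 with no fold.

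Gene lists were fixed before the data were examined: 32 lists with 426 entries, of which 19 entries had no match in the table, 11 of them in the list of mitochondrial genes. Lists with at least 3 measured members were scored (30 lists). Families were defined by the letters before the hyphen of a gene symbol and scored where at least 10 members were measured. The median difference of a list was placed among the medians of 10000 random lists of the same size, drawn from measured genes in the same of 20 bins of mean expression. A list at or below percentile 2.5, or at or above percentile 97.5, is described as standing apart from random lists. This percentile describes these 2 libraries and is not a test of the genotype. By that rule alone, chance puts 0.75 of the 30 lists, and 2.98 of the families, on each side. That number holds for members that vary separately, which genes of 1 list or family need not do.

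Genes were named by a rule fixed before the data were examined. It takes lsm-1, every Lsm gene, and the 10 largest and 10 smallest differences among genes past the authors' test with an FPKM of at least 5 in either library. It also takes up to 2 members at each end of each list or family described. Because most genes at the ends of that ranking were listed at 0 in 1 library, the same ranking was repeated after the data were seen among genes above 0 in all 4 FPKM columns. The genes of the pud and C32H11 groups, further members of the lists described, genes of the propionate shunt and genes used as examples of values at 0 were also chosen after their values were seen.

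Symbols, RNA classes, transcript numbers and lengths, and the order of neighbouring genes came from RefSeq and Ensembl release 115 annotation of the WBcel235 assembly, which may differ from the annotation the authors used. The RNA class was known for 44817 genes and a length for 45689. Depth was estimated from the steps between low FPKM values of genes with 1 annotated transcript: for 44.5% of 1894 such genes the ratio of the 2 libraries fell within 0.5% of a ratio of small whole numbers times a common step, against 3.67% by chance. The steps correspond to about 8.56 M fragments in the mutant library and 7.01 M in the wild-type library. Fragment numbers derived from them are approximate, and the 95% intervals built on them (Clopper-Pearson, or Poisson redraws for a sum) cover counting error only.

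The size rule and the list percentile were tested on simulated libraries of 11603 genes at these depths. These had counting noise only and 200 genes changed. All simulated genes were above 0 in all 4 FPKM columns. The rates below therefore do not cover genes listed at 0, which make up most genes past the size rule. The size rule found 100% of genes raised by 3 on the log2 scale, 78.0% of those raised by 1.5 and 64.4% of those lowered by 1.5, and it took in 1.1% of unchanged genes. Of 200 random lists, 97.0% fell between percentiles 2.5 and 97.5, and a list of raised genes reached percentile 100. The random lists held unchanged genes with separate counting noise, so they do not cover lists whose members vary together.

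The alternatives planned before the data were examined were a pseudocount of 0.1, an FPKM of at least 5 or no filter, centring, scaling both libraries to the same sum, and only genes with a usable test. Further planned ones were other size limits, a q of at most 0.01, unmatched random lists, and the mean in place of the median. The alternatives added after seeing the data were the further FPKM pair, only genes above 0 in all 4 FPKM columns, and only protein-coding genes. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.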

Results

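Transcript levels were compared between L3 larvae carrying the lsm-1(tm3585) allele and wild-type N2 larvae of the same age. lsm-1 encodes a subunit of the cytoplasmic Lsm ring, which promotes the decapping of messenger RNAs on their way to 5'-to-3' decay. The data comprised 1 rRNA-depleted library per genotype, of about 8.56 M fragments in the mutant and 7.01 M in the wild type. An FPKM above 0 was given for 19718 genes in the mutant library and for 21046 in the wild type. Ribosomal RNA took up 30.8% of the FPKM weighted by length in the mutant library and 39.8% in the wild-type library. The ribosomal RNA gene rrn-3.1, the pseudogene rrn-3.56, F31C3.14 and F31C3.16 were listed at 0 in both libraries of the pair used for the comparisons, and these shares take them from the further pair. There rrn-3.1 stood at 38148 FPKM in the mutant and 46146 in the wild type, and rrn-3.56 at 66154 and 73041. With all 4 counted as ribosomal RNA the shares were 40.05% and 50.3%. Centred differences below are relative to the median of measured genes, which was 0.24 higher in the mutant on the log2 scale.

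The first comparison concerned the mutated gene and its partners. The lsm-1 transcript (F40F8.9, chromosome II) stood at 5.94 FPKM in the mutant and 10.2 in the wild type, a ratio of 0.581. About 27 and 38 fragments lay behind these values, and the 95% counting interval of the ratio ran from 0.342 to 0.978. In the authors' deposited table the gene was not past the test (q = 0.457). An FPKM over the whole gene can miss a partial deletion, so this level is a weak check of the genotype. Of the 7 measured Lsm genes, none passed the size rule or the authors' test. The transcripts of lsm-3 (34.1 against 22.1 FPKM), lsm-5 (23.9 against 18) and lsm-6 (21.9 against 18.3) had centred differences of 0.37, 0.16 and 0.00. Those of gut-2 (19.7 against 16), lsm-4 (14.1 against 11.5) and lsm-7 (20.6 against 16.9) lay as near to the median, at 0.05, 0.03 and 0.03. The transcript of lsm-8, which belongs to the nuclear Lsm ring, was listed at 0 in both libraries.

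The second comparison asked how many genes differed between the libraries. By the size rule, 2011 of 14838 measured genes were higher in the mutant and 1817 were lower, and after centring the split turned to 1558 higher and 2175 lower. Most of these genes, 1211 of the higher and 1343 of the lower ones before centring, were listed at 0 in 1 library. All 2554 measured genes listed at 0 in 1 library pass the size rule by construction. An FPKM of at least 1 against 0 always gives a difference of at least 1. Among the 11804 measured genes above 0 in all 4 FPKM columns, 775 were higher and 456 lower, or 418 and 803 after centring. In the authors' deposited table the test was passed by 661 genes, 413 higher and 248 lower in the mutant, and 342 of them were listed at 0 in 1 library. Centring their differences left the split at 413 and 248. The calls themselves were made on values without centring, so the excess of higher genes is not read as a general rise. Of the 305 called genes above 0 in all 4 FPKM columns, 199 were higher and 106 lower in the authors' deposited table.

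**Figure D1:**
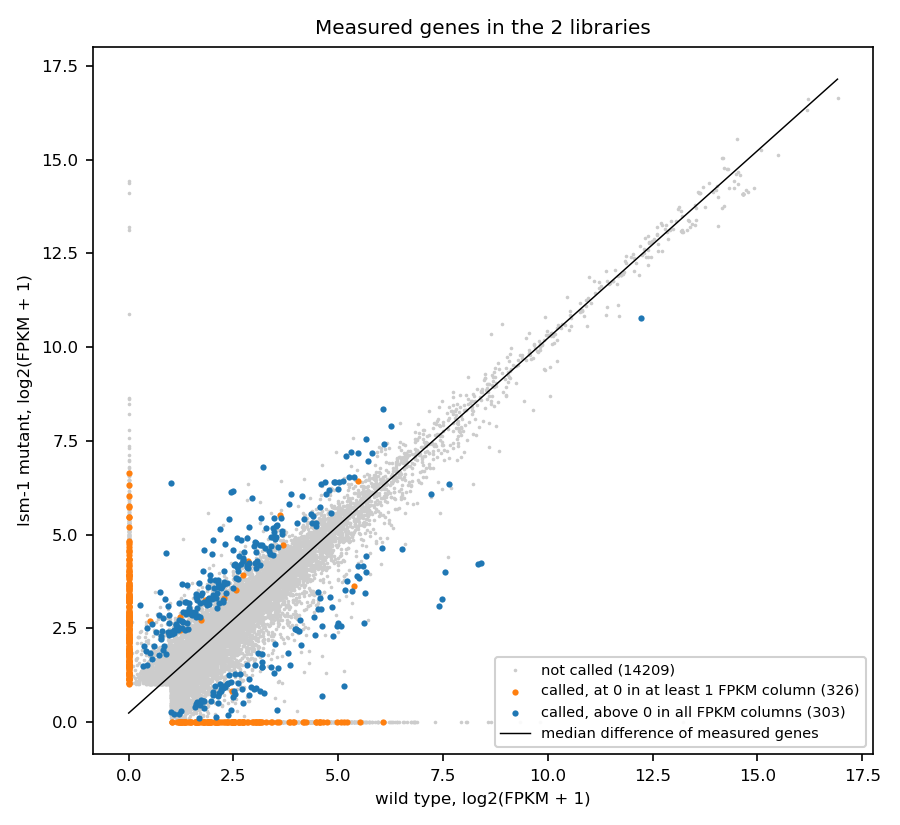
Each point is 1 of the 14838 measured genes, with log2(FPKM + 1) in the wild-type library on the x axis and in the lsm-1 mutant library on the y axis; blue points are called genes above 0 in all 4 FPKM columns, orange points the 326 called genes at 0 in at least 1 of them, and grey points the 14209 genes not called. The orange points lie mainly along the axes at 0, and the line marks the median difference of 0.24.

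Among genes above 0 in all 4 FPKM columns, 4 of the 10 with the highest differences past the authors' test belonged to the C32H11 group, and 4 of the 10 with the lowest were pud genes. On chromosome IV, 4 genes of the C32H11 group were higher in the mutant: C32H11.4 stood at 82.1 FPKM against 1.01, dod-21 at 69.7 against 4.43, cld-1 (C32H11.9) at 70.5 against 4.63, and dod-24 at 111 against 8.26. Of these, dod-21 and cld-1 stood at similar levels in both libraries, and whether they share reads was not examined. On chromosome V the pud genes, named for proteins that are more abundant in a long-lived daf-2 mutant, were lower. The pair pud-1.1 and pud-1.2 stood at 7.61 and 8.69 FPKM in the mutant against 167 and 178 in the wild type. The pair pud-2.1 and pud-2.2 stood at 18 and 17.7 against 340 and 319. Each pair consists of near-identical copies that share reads, so the values of single copies are uncertain. The genes pud-3 and pud-4 were listed at 0 in the mutant and at 22.7 and 36.1 FPKM in the wild type. All 10 of these genes passed the authors' test.

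Several enzymes and secreted proteins stood beside these groups, each past the authors' test. Higher in the mutant were the glutathione S-transferase gene gst-38 (41.5 against 4.29 FPKM), the cytochrome P450 gene cyp-13A2 (28 against 3.07), the insulin-like gene ins-35 (61.5 against 6.74) and nspe-1 (21.9 against 0.862). The genes F22H10.2 (34.6 against 3.53) and T05B4.9 (7.71 against 0.205) were also higher. Lower in the mutant were acdh-1, which encodes a short-chain acyl-CoA dehydrogenase (15 against 186), and the C-type lectin gene clec-47 (0.243 against 10.6). The same held for F15E6.4 (5.26 against 47.7), F48C1.11 (0.627 against 23.3), F59C6.18 (0.950 against 34.2) and ZK105.1 (3.87 against 28.2). The most abundant gene called was H27M09.7, at 1747 FPKM in the mutant and 4741 in the wild type.

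**Figure D2:**
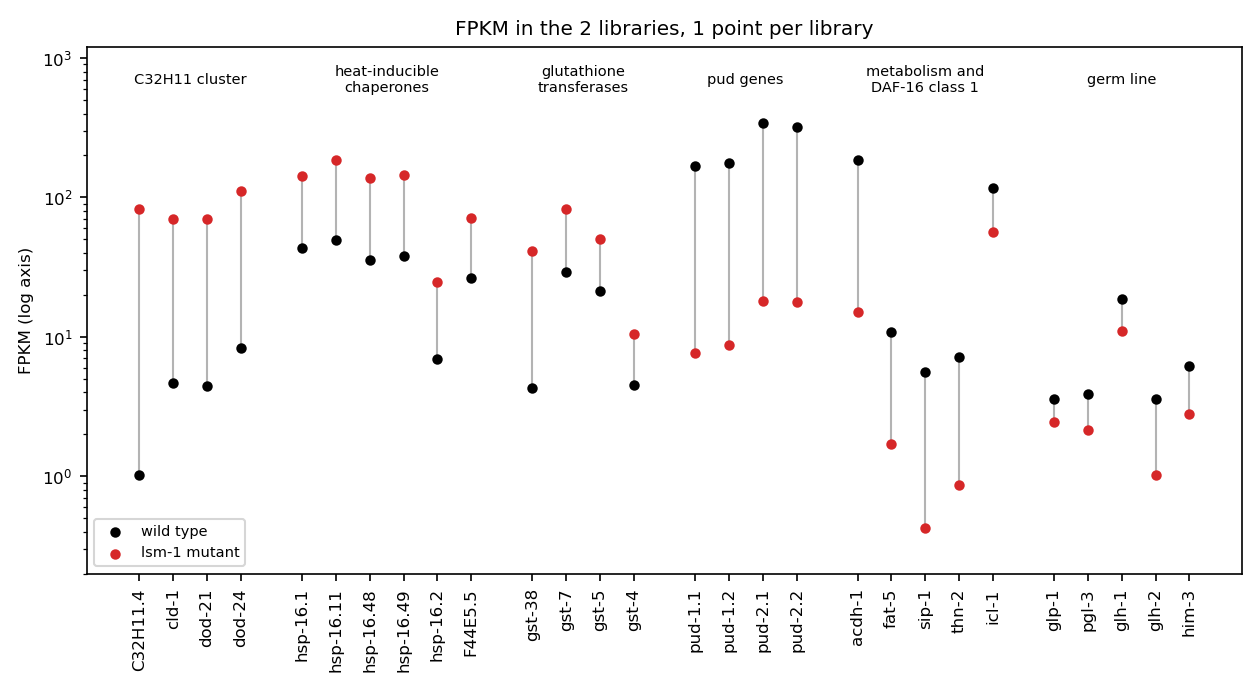
FPKM on a log axis in the wild-type library (black) and the lsm-1 mutant library (red) for named genes in 6 groups, 1 point per library and no replicates. The mutant value lies above the wild-type value in the first 3 groups and below it in the last 3, with the widest gap at C32H11.4 (82.1 against 1.01 FPKM).

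Ranked by difference alone, 9 of the 10 highest and 10 of the 10 lowest genes past the authors' test were listed at 0 in 1 library. At the high end these included ndub-2 (99.2 FPKM in the mutant) and ndub-8 (79.0), which encode subunits of mitochondrial complex I. Others were pmt-1 (64.3), which encodes a phosphoethanolamine methyltransferase, got-2.2 (53.5), R02F2.1 (52.4), E01G4.3 (43.5), Y54G9A.12 (43.1), mrpl-14 (36.1) and ZK1307.8 (27.2), all listed at 0 in the wild type. At the low end C52B11.4 (65.6 FPKM in the wild type), atp-4 (45.1), pdhb-1 (34.2), T28A11.2 (32.5), K09G1.1 (30.6), dhs-3 (25.4), pals-23 (23.9) and ppm-2 (22.6) were listed at 0 in the mutant. Genes used by every cell showed the same: rps-3, which encodes a protein of the small ribosomal subunit and whose test is marked as failed in the authors' deposited table, was listed at 0 in the mutant and at 379 FPKM in the wild type. Of 180 measured genes for ribosomal proteins, proteasome, V-ATPase, aminoacyl-tRNA synthetases and initiation factors, 9 were listed at 0 in 1 library. In the further pair ndub-8, got-2.2, R02F2.1, E01G4.3, T28A11.2 and atp-4 were listed at 0 in both libraries, and so were hsp-60 and akt-1 among the genes below. Others were unchanged there: ndub-2 (86.1 FPKM in the mutant), pmt-1 (56.4), Y54G9A.12 (37.7), mrpl-14 (30.3) and ZK1307.8 (23.6) were again listed at 0 in the wild type. Because a value of 0 can be a failed estimate, the values of this group are not read as losses of expression.

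Among the stress lists, both chaperone lists and the detoxification list stood above random lists. Of 9 heat-inducible chaperone genes, 8 were higher by the size rule and 6 passed the authors' test, with a centred median of 1.45 at percentile 100. The small heat-shock protein genes hsp-16.48 (137 against 35.7 FPKM) and hsp-16.49 (146 against 38.3) had the largest differences, and hsp-16.41 (27.8 against 11.8) and hsp-70 (2.97 against 1.43) the smallest. The pairs hsp-16.1 and hsp-16.11, and hsp-16.48 and hsp-16.49, are near-identical, so their single values are uncertain. Such copies do not count as separate evidence in the counts and the percentile of this list. F44E5.4 (73.7 against 27.9 FPKM) and F44E5.5 (71.6 against 26.4) also stood at similar levels, and whether they share reads was not examined. Of 14 constitutive chaperone genes, 5 were higher by the size rule and 1 was lower, with a centred median of 0.56 at percentile 99.9. In that list hsp-1 (73 against 30.7 FPKM), hsp-43 (11.9 against 3.80) and hsp-12.1 (25.6 against 8.09) were higher and sip-1 (0.425 against 5.58) was lower past the authors' test, while hsp-12.3 stood at 5.81 against 7.23 and hsp-12.2 was listed at 0 in the wild type (23.7 in the mutant). Of 12 phase 2 detoxification genes, 7 were higher by the size rule and none was lower, with a centred median of 0.90 at percentile 100. There gst-38, gst-7 (82.8 against 29.1 FPKM) and nit-1 (9.79 against 2.39) passed the authors' test. The genes gst-12 (4.27 against 0.213), gst-13 (31.7 against 19) and gsr-1 (37.7 against 33.6) did not pass it. With the mean in place of the median, the heat-inducible chaperones lay at percentile 97.3 and the constitutive chaperones at 97.0, short of the limit.

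The ER stress list had a centred median of 0.37 at percentile 98.4, but 10 of its 11 measured genes lay within the size rule. Its highest members were crt-1 (339 against 198 FPKM), which encodes calreticulin, and hsp-4 (14.4 against 8.21). Its lowest were atf-6 (4.13 against 3.51) and ire-1, listed at 0 in the mutant and at 5.18 in the wild type and past the authors' test. The further FPKM pair turns the direction of ire-1, at 6.13 in the mutant and 4.54 in the wild type. This position was lost with the mean (percentile 51.9), with an FPKM of at least 5 (96.6), with a pseudocount of 0.1 (96.8), without a filter (93.0) and with unmatched random lists (96.6). The mitochondrial stress list (percentile 90.8), the hypoxia, osmotic and metal list (93.5), the antioxidant enzymes (38.2) and the stress granule list (94.97) did not stand apart. In them hsp-60 was listed at 0 in the wild type (82.6 FPKM in the mutant), cysl-2 stood at 52.8 against 15.5, sod-1 at 52.1 against 22.5 (past the authors' test), msra-1 at 40.5 against 73 and gtbp-1 at 22.1 against 12. The hypoxia, osmotic and metal list passed the limit in some alternatives. It lay at percentile 98.58 with a pseudocount of 0.1, 98.57 without a filter and 98.1 among genes above 0 in all 4 FPKM columns.

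Genes that act below the insulin pathway were split. Of 14 measured DAF-16 class 1 genes, which the transcription factor DAF-16 activates, 6 were lower by the size rule and none was higher, with a centred median of -0.98 at percentile 0. The genes sip-1, thn-2 (0.861 against 7.21 FPKM) and fat-5 (1.70 against 10.8), which encodes a fatty acid desaturase, were lower past the authors' test. The genes gst-10 (72.4 against 36.7) and dod-6 (8 against 4.81) were the only 2 members above the median of measured genes. Of 8 DAF-16 class 2 genes, which DAF-16 represses, dod-21, dod-24 and dod-17 (29.4 against 9.44 FPKM) were higher past the authors' test. Both dod-21 and dod-24 belong to the C32H11 group described above. The insulin-like gene ins-7 stood at 0.569 against 10.2 without passing it, and dod-22 at 6.01 against 4.97. The class 2 median lay at percentile 95.4, short of the limit, but passed it in 4 alternatives, at 99.5 with a pseudocount of 0.1, 98.4 with an FPKM of at least 5, 99.5 with the further FPKM pair and 99.8 among genes above 0 in all 4 columns. The 15 measured insulin pathway genes lay at 59.0. In that pathway daf-16 stood at 7.34 against 4.93, daf-2 at 10.4 against 7.603 and ins-18 at 21 against 8.27, and akt-1 was listed at 0 in the wild type (29.1 in the mutant).

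Epidermal antimicrobial peptide genes were lower as a group. Of 17 measured, 6 were lower and 1 was higher by the size rule, with a centred median of -0.84 at percentile 0, and 14 lay below the median of measured genes. The caenacin gene cnc-2 (9.82 against 49.1 FPKM) passed the authors' test, and cnc-5 was listed at 0 in the mutant (4.14 in the wild type). At the other end nlp-28 stood at 51.2 against 31.8, and cnc-1 was listed at 0 in the wild type (2.69 in the mutant). The 17 intestinal immunity genes went both ways and lay at percentile 9.82. In the authors' test lys-4 (14.9 against 50 FPKM) was lower and clec-60 (11 against 3.63) was higher, while sysm-1 (12.8 against 34.1) and spp-18 (23.1 against 10.3) were not past it. The fatty acid metabolism list lay at percentile 46.7, with acdh-1 and fat-5 lower and the elongase gene elo-2 (29.6 against 10.3) higher past the authors' test, and elo-5 at 43.8 against 17.3.

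Tissue lists differed in direction. Of 14 measured genes of the proliferating germ line, all 14 lay below the median of measured genes, with a centred median of -0.89 at percentile 0.14. The RNA helicase gene glh-2 (1.02 against 3.56 FPKM) was lower past the authors' test. The synapsis gene him-3 stood at 2.79 against 6.16 but was marked as having too few data for that test. The Notch receptor gene glp-1 (2.46 against 3.57), pgl-1 (13 against 14.7) and fbf-2 (1.34 against 1.35) did not pass it. With an FPKM of at least 5 this list lay at percentile 2.75 and with the mean at 3.86. The oocyte list (8 measured) and the sperm list (4 measured) had centred medians of -1.11 and -0.92 at percentiles 6.21 and 17.8. In them oma-1 and spn-4 were listed at 0 in the mutant (2.12 and 2.22 in the wild type), and fog-3 stood at 0.970 against 3.48. None of the vitellogenin genes was measured, with 0.761 FPKM as their highest value.

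The epidermis and seam list stood above random lists, with a centred median of 0.69 at percentile 99.9, and 5 of its 10 genes were higher by the size rule. The GATA factor genes elt-1 (8.05 against 1.73 FPKM) and elt-3 (16.6 against 6.06) and the hedgehog-related gene grd-10 (84 against 29) were higher past the authors' test. The genes arf-3 (79.3 against 74.6) and ceh-16 (2.21 against 2.11) were at its low end. Body wall muscle (percentile 98.1) was higher in all 10 measured genes after centring, led by the myosin gene myo-3 (13.4 against 5.56 FPKM) and by mup-2 (84.1 against 46.7), with pat-10 (445 against 340) and unc-27 (174 against 135) at its low end. With the mean, the epidermis and seam list lay at percentile 91.4 and body wall muscle at 92.2, and with unmatched random lists muscle lay at 94.7. The neuron list (percentile 97.6) held 4 genes listed at 0 in the wild type, among them sbt-1 (13.8 FPKM in the mutant) and rab-3 (10.3), both listed at 0 in both libraries of the further pair, with unc-119 (5.88 against 4.82) and ida-1 (19.6 against 17.2) at its low end. Among genes above 0 in all 4 FPKM columns it lay at percentile 88. The intestine (58.5) and pharynx (88.3) lists did not stand apart: pept-1 stood at 14.4 against 8.45 FPKM, mtl-2 at 26.3 against 59.0 and tnc-2 at 12.56 against 6.56, and phat-3 was listed at 0 in the wild type (3.92 in the mutant, past the authors' test). Among genes with a usable test the intestine median turned from 0.32 to -0.26 before centring, at percentile 1.06.

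**Figure D3:**
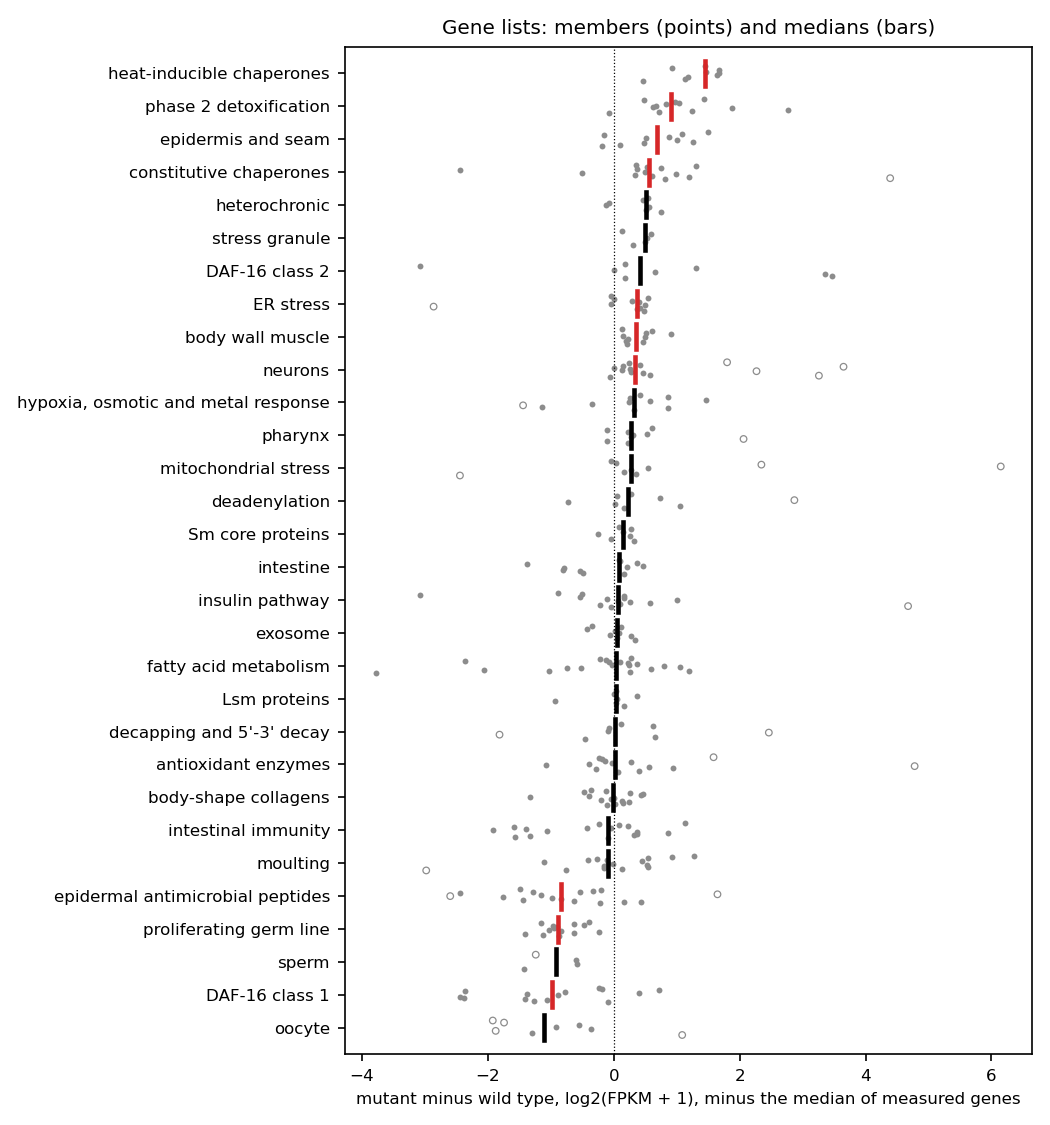
Centred difference (x axis, log2(FPKM + 1) in the mutant minus the wild type, minus the median of measured genes) of the members of 30 gene lists; points are genes, open points genes listed at 0 in 1 library, and bars list medians, red where the list stood apart from matched random lists. The heat-inducible chaperones have the highest median (1.45) and the oocyte list the lowest (-1.11), the latter not apart from random lists.

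Lists for developmental stage did not stand apart from random lists, the heterochronic genes only narrowly. A median can hide members that go both ways, so these positions do not show that the libraries match in stage. The heterochronic genes, which time larval development, had a centred median of 0.52 at percentile 97.0. Among them lin-41 (5.603 against 2.33 FPKM) was higher past the authors' test, and lin-14 (8.29 against 4.72), lin-28 (14.3 against 8.09) and daf-12 (3.41 against 1.54) did not pass it. In the further FPKM pair lin-41 was listed at 0 in both libraries and daf-12 at 0 in the mutant (1.36 in the wild type), which turns its direction. The heterochronic list passed the limit in 2 alternatives, at percentile 99.35 without a filter on low values and at 97.7 with a pseudocount of 0.1. The 17 moulting genes lay at percentile 18.97, with fbn-1 (4.24 against 0.843), mlt-7 (13.6 against 5.51) and bli-5 (3.20 against 6.71) at their ends, and nhr-23 listed at 0 in the mutant (5.70 in the wild type). Both fbn-1 and nhr-23 were listed at 0 in both libraries of the further pair. The 16 body-shape collagens lay at 30.2, between dpy-10 (39.8 against 24.1) and dpy-14 (0.549 against 2.30). Of the moulting genes 7 lay above the median of measured genes and 10 below, and of the collagens 8 and 8.

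The machinery of RNA decay lay near the median of measured genes. The decapping list was at percentile 44.6, the deadenylation list at 78.4, the exosome list at 40.2, the Lsm list at 38.9 and the Sm core list at 69.8. Among decapping factors patr-1 stood at 13.6 against 6.90 FPKM and cgh-1 at 16.6 against 19.4. The decapping enzyme gene dcap-2 was listed at 0 in the mutant (1.99 in the wild type, past the authors' test), and edc-3 was listed at 0 in the wild type (5.5 in the mutant). The further FPKM pair turns the direction of dcap-2, at 2.74 in the mutant and 1.75 in the wild type. Of the deadenylation genes ntl-9 stood at 8.45 against 2.88 and parn-1 at 1.57 against 2.60. Of the exosome genes exos-1 stood at 8.05 against 9.34, and of the Sm genes snr-4 stood at 65.4 against 44.3.

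In the survey of gene families, 12 stood above random lists and 8 below. With the mean in place of the median 5 stood above and 5 below, so not every position named here holds under the mean. Above were the hsp family (20 measured, centred median 1.09, 9 genes higher past the authors' test) and the gst family of glutathione S-transferases (36 measured, 0.57, 8 genes). The hsp family includes the near-identical hsp-16 pairs, so its members are not all separate evidence. The hsp and gst families share members with the chaperone and phase 2 lists, and the cnc family below with the epidermal antimicrobial list. Their positions partly repeat those of the lists. The globin genes glb (29 measured, 0.42), the unc genes (76 measured, 0.28), the fungus-induced peptide genes fipr (19 measured, 0.46), the galectin genes lec (12 measured, 0.44) and the large ribosomal subunit genes rpl (48 measured, 0.18) also lay above. Examples were fipr-1 (23.05 against 2.503 FPKM), lec-11 (35.2 against 9.79) and rpl-25.1 (122 against 51.8), each past the authors' test. Against their families gst-29 (1.5 against 5.76) and rpl-11.1 (127 against 184) were lower without passing it. The eif, egl, txt and clc families had centred medians of 0.30, 0.40, 0.50 and 0.34, with txt-14 at 326 against 65.7 FPKM past the authors' test. The sls family (10 measured), of near-identical spliced-leader RNA genes, held 7 members listed at 0 in 1 library and lay at percentile 0.01 among genes above 0 in all 4 FPKM columns.

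Below random lists were the caenacin genes cnc (11 measured, centred median -1.28) and the nspc peptide genes (19 measured, -1.01), among which nspc-9 (4.93 against 32.2 FPKM) was lower past the authors' test. Histone genes followed with 72 measured members and a centred median of -0.46. None of the histone genes passed the size rule, and 62 lay below the median of measured genes, from his-73 (28.3 against 45.7 FPKM) to his-69 (1.34 against 0.638) at the other end. Many histone copies are near-identical, so their members do not count as separate evidence. The acyl-CoA dehydrogenase genes acdh (10 measured, -0.55), the C-type lectin genes clec (83 measured, -0.38) and the carboxylesterase genes cest (27 measured, -0.47) also lay below. Some of their members went the other way past the authors' test, such as clec-230 (26.5 against 7.23). The rrn genes, which encode ribosomal RNA, were lower in all 18 measured copies (-0.80), which leave out rrn-3.1 and rrn-3.56. The libraries were depleted of ribosomal RNA and differed in its share, and the copies are repeats, so these do not count as separate evidence. The collagen genes col had a median of 0.12 before centring and -0.12 after it, and with the mean they lay at percentile 78.2. In that family 10 genes were higher and 3 lower past the authors' test, among them col-156 (23.4 against 90.9 FPKM) and col-49 (0.763 against 4.69).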

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

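A further pair of FPKM columns from the same libraries held signal for genes listed at 0 in the pair beside the authors' test. In the mutant library 68 genes were listed at 0 in the first pair but at 5 FPKM or more in the further pair, and in the wild-type library 80 genes were. These are few beside the 1343 measured genes listed at 0 in the mutant library of the first pair and the 1211 in the wild type. An example is dhs-3, which encodes a short-chain dehydrogenase. It was called lower in the mutant at 0 against 25.4 FPKM, while the further pair gave 28.9 FPKM in the mutant and 22.5 in the wild type. In the reverse direction, 245 genes in the mutant and 233 in the wild type were listed at 0 in the further pair but at 5 FPKM or more in the first.

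The test on transcript numbers and the test on the share of zeros per library were chosen after the result was seen. The pattern was the 342 genes past the authors' test that were listed at 0 in 1 library, among them ndub-2, pmt-1, pdhb-1 and atp-4. Expression lost in the mutant animals does not account for it as a whole, because it cannot give zeros in the wild-type library. The mutant library held 40.9% of the zeros (Clopper-Pearson 95% interval 35.7 to 46.4). That share does not test a loss, since 108 of 319 genes called with both libraries above 0 were also lower in the mutant. Failed estimates in the authors' quantification remain a candidate explanation: 64.4% of 331 coding genes in this group had more than 1 annotated transcript (interval 58.9 to 69.5), against 38.4% of 302 coding genes called with both libraries above 0 (32.9 to 44.2). A loss of expression in single genes, such as pud-3 and pud-4 beside their lower neighbours, stays open.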

How the results depend on the processing

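No paired analysis was possible because each genotype had 1 library. The further FPKM pair, the limit to genes above 0 in all 4 FPKM columns and the limit to protein-coding genes were chosen after seeing the data. The lsm-1 difference ran from -0.93 (centred) to -0.69 and stayed inside its counting interval. Counts of genes by the size rule, higher and lower, were 1297 and 901 with an FPKM of at least 5, 946 and 940 for a difference of at least 2, 1220 and 831 among protein-coding genes, and 775 and 456 among genes above 0 in all 4 columns. A limit of 1.5-fold gave 3938 and 2589. In the authors' deposited table a q of at most 0.01 left 275 higher and 154 lower genes, and genes above 0 in all 4 columns numbered 199 and 106. These follow from stricter or looser limits, or from fewer genes.

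Lists above random lists numbered 4 with unmatched random lists and 2 with the mean of members, against 7. The mean left 5 families above and 5 below, against 12 and 8. Under the mean ER stress, at 0.24, lay in the middle of random lists (percentile 51.9). The other values, on the same side but short of the limits, were 1.53 for heat-inducible chaperones, 0.89 for constitutive chaperones, -0.60 for the proliferating germ line, 0.62 for body wall muscle and 0.88 for epidermis and seam. The ER stress median was also short of the limit at 0.62 with a pseudocount of 0.1 and with an FPKM of at least 5, at 0.38 without a filter and at 0.61 with unmatched random lists, which also left body wall muscle short at 0.58. The neuron median was short of it at 0.61 with a pseudocount of 0.1, 0.51 with an FPKM of at least 5 or only genes with a usable test, 0.50 with the further pair, 0.49 among genes above 0 in all 4 columns and 0.58 with unmatched random lists. The germ-line median was short of it at -0.76 with an FPKM of at least 5. The col family turned to 0.29 with the mean, the sls family to -1.85 among genes above 0 in all 4 columns, where few members remain, and dhs-3 to 0.35 in the further pair. The cause was not tested for these lists, families and this gene. Lists that passed the limits only in an alternative were DAF-16 class 2 (0.98 with a pseudocount of 0.1, 0.98 with an FPKM of at least 5, 0.94 with the further pair, 0.89 among genes above 0 in all 4 columns) and the heterochronic genes (0.82 with a pseudocount of 0.1, 0.68 without a filter). The same held for the hypoxia, osmotic and metal list (0.77 with a pseudocount of 0.1, 0.60 without a filter and among genes above 0 in all 4 columns), the oocyte list (-0.62 with both libraries scaled to the same sum, -0.87 with unmatched random lists) and the intestine list (-0.26 among genes with a usable test, turned from 0.32). The DAF-16 class 1, epidermal antimicrobial and phase 2 lists kept their side and their limits under every alternative run. Depth limits the reading of low genes: lsm-1 rested on about 27 and 38 fragments and sip-1 on about 2 and 25.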

Other observations

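Enzymes of the propionate shunt, a pathway that breaks down propionyl-CoA without vitamin B12, were mostly lower in the mutant. Its first enzyme acdh-1 stood at 15 against 186 FPKM, ech-6 at 55.7 against 109, hach-1 at 20.4 against 49.6 and hphd-1 at 11.38 against 40.7, and all 4 but ech-6 passed the authors' test. Its last enzyme alh-8 was listed at 0 in the wild type (24.6 in the mutant, higher past the authors' test) and at 0 in both libraries of the further pair, and hphd-1 was listed at 0 in the mutant there. The dehydrogenase gene dhgd-1 (16.9 against 43.1) was also lower past the authors' test. These genes were chosen after their values were seen.

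Called genes lay beside each other more often than shuffled calls did. Among measured genes in chromosome order, 47 neighbouring pairs were called in the same direction, against a median of 14 and a highest value of 38 in 10000 shuffles of the calls. Among called genes above 0 in all 4 FPKM columns there were 18 pairs, against a median of 3 and a highest value of 11. The shuffles treat each call as separate, while near-identical neighbouring copies share reads and can be called together. How much of the excess comes from such copies was not tested. The longest runs of that kind were hsp-16.1, hsp-16.48, hsp-16.49 and hsp-16.11 on chromosome V, which form 2 pairs of near-identical copies, and the hedgehog-related genes grd-13 (33.1 against 11.5 FPKM), grd-3 (20.4 against 5.19) and grd-10 on chromosome IV. All 14 measured genes of the mitochondrial chromosome were higher in the mutant before centring, with a centred median of 0.35. On that uncentred scale 8155 of 11949 measured protein-coding genes were higher too. Of the 14, MTCE.34 (236 against 75.3 FPKM) alone passed the authors' test, while ctb-1 (262 against 164) did not.

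Of the tests in this part, the second list of germ-line genes was fixed before its values were seen, and the other tests were chosen after the result was seen. The first pattern was the higher level of heat-inducible chaperone and phase 2 genes beside lower DAF-16 class 1 genes. The summed FPKM of the heat-inducible chaperones was 1.51 higher on the log2 scale after centring (95% interval 1.41 to 1.62). That total does not depend on how reads were divided among near-identical copies. It is no separate test of shared reads, because all 9 members already lay above the median of measured genes. A lower activity of DAF-16 in the mutant animals is a hypothesis that cannot be told apart from others here: class 1 lay at percentile 0 and class 2 at 95.4, or 99.8 among genes above 0 in all 4 FPKM columns, but with 8 measured class 2 genes, ins-7 among them going the other way.

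The second pattern was the lower level of germ-line and histone genes. A second list of 30 germ-line genes, 26 of them measured, lay at percentile 0.87 with a centred median of -0.49, and 23 of the 26 lay below the median of measured genes. Fewer germ cells in the mutant animals may give this. The second list repeats the pattern in the same 2 libraries, so it cannot tell fewer germ cells from slower development. The 2 genes of that list past the authors' test went opposite ways, zim-3 lower (1.40 against 4.30 FPKM) and gld-2 higher (8.64, listed at 0 in the wild type), and him-8 (9.68 against 3.75) was higher by the size rule. Slower development of the mutant animals stays open: of lin-14, lin-28, lin-41 and hbl-1, 3 were higher after centring and hbl-1 was listed at 0 in both libraries. The moulting list lay at percentile 18.97, but its members went both ways, so its median cannot decide the question.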
